A study of Mus musculus with 8 samples.

How the data were processed

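Placentas and uteri of mouse pregnancies were collected at 10.5 days post coitum, and total RNA from pools of 3 organs was purified with Trizol and labelled with Cy3 by the authors. Females were B6 or R3 and males were B6. The arrays were single-colour NimbleGen expression arrays with 2 arrays in each of 4 groups (placenta or uterus, B6 or R3). The deposited values are on the log2 scale, and the submitters' processing notes name RMA (background correction, normalization over arrays and a summary per probe set) without its version or the arrays it was run on together. Each of the 25631 transcript records, 18879 with curated and 6752 with predicted RefSeq accessions, had a value on each of the 8 arrays. No value was missing, and the identifiers came without probe sequences. The labels do not say which arrays shared a slide, or whether the pools of a group came from separate animals. The p-values therefore measure only the spread between these samples, and for arrays only their number can be said to limit the precision.

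Records were named by RefSeq accession from an annotation table of the mouse assembly GRCm38.p6. This named 17780 records (17761 curated and 19 predicted) for 17277 genes, of which 433 had more than 1 record. The other 7851 records stayed in all tests and counts but were left out of the named genes and gene lists. The assembly served for gene order along chromosomes alone, since the array's own design and build were not named. Where a gene had several records, the record with the highest mean over all arrays stood for it.

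Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, 4 residual degrees of freedom, and moderated variances with 3.46 prior degrees of freedom (3.26 on the rank-matched values). The comparisons were R3 minus B6 in the placenta, in the uterus and averaged over both, the strain by tissue interaction, and placenta minus uterus averaged over both strains. The p-values of each comparison were adjusted over all 25631 records with the Benjamini-Hochberg method, with a threshold of 0.05. These comparisons, 32 gene lists with 750 genes (720 measured), the rule for named genes and the first set of alternatives were fixed before the data were examined. Because the R3 arrays lay above the B6 arrays, the strain comparisons were repeated on values quantile-normalized over the 8 arrays, called rank-matched values below. Quantile normalization was among the first set of alternatives, and its use as a full second set of results was decided after the data were seen.

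Named genes had to have a single symbol. In each tissue they were up to 10 rises and 10 falls of largest size that passed the threshold without overlap between the arrays of both strains. For the averaged strain difference they were the 10 of smallest p in each direction, and for the interaction the 5 of smallest p in each direction. For placenta minus uterus they were the 10 largest rises and 10 largest falls. Of each list described, up to 4 members of largest absolute moderated t were named, and genes that passed in both tissues were ranked by the larger of their p-values.

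The lists were markers of placental, uterine, blood, immune, yolk sac and vascular cells, functional groups such as imprinted, interferon or cell cycle genes, and outgroups of tissues absent from both organs. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with the rotation test fry. The number of members past the threshold was also counted after adjustment over the list alone. For the chromosome test, the 200 genes of smallest p in the averaged strain comparison were counted in stretches of 20 neighbouring genes among 17260 placed genes and compared with 10000 random draws. Fisher's exact test was run per chromosome.

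Alternatives were quantile normalization, centring each array on its median, leaving out the dimmer part of the transcripts, an intensity trend with a robust prior, the replicate number as a block, averaging the records of a gene, using only the 4 arrays of a tissue, and leaving out each array in turn. In the last case the lone array of a group was assumed to vary like those of the other groups. The procedure was tested on simulated data with 25631 transcripts, of which 100 changed by 1 and 100 by 2 (log2) in each comparison. At a log2 change of 2 it recovered 20% in the placenta, 5% in the uterus, 85% in the average of both, 0% in the interaction and 88% between tissues. At a log2 change of 1 it recovered 0%, 0%, 7%, 0% and 8%. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.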

Results

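Gene expression was measured in placenta and uterus at 10.5 days post coitum in pregnancies of B6 and R3 mothers. B6, labelled C57BL6/J, is the control strain. R3 is an interspecific recombinant congenic strain (IRCS), which carries segments of Mus spretus genome on a mostly B6 background. All fathers were B6, so the uterus had the mother's genotype and the fetal part of an R3 placenta had an R3 mother and a B6 father. Each of the 4 groups had 2 arrays, each from a pool of 3 organs, which made 8 arrays with values for 25631 transcripts (17277 named genes). Differences below are on the log2 scale with their standard error (SE), with n = 2 arrays in each group, and p-values are adjusted over all transcripts by limma. The number of arrays limits the precision.

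Most transcripts had higher values on R3 than on B6 arrays in both tissues. Array medians were 7.15 and 7.12 in B6 placenta, 9.12 and 9.13 in R3 placenta, 7.19 and 7.15 in B6 uterus, and 9.12 and 9.18 in R3 uterus. The mean median was 7.15 for B6 and 9.14 for R3, a difference of 1.99 (exact permutation test, two-sided, p = 0.0286, the smallest that the 70 splits of these arrays allow), while the range within a strain was 0.0702 for B6 and 0.0666 for R3. Normalization gives arrays processed together like medians, and which arrays were processed together is not known. The p-value therefore does not measure a spread between animals and is no evidence on its own of a difference in the tissue. The median difference over transcripts was 1.23 in the placenta and 1.29 in the uterus, with 94.1% and 96.2% of transcripts higher in R3. The difference depended on signal: among 10 groups of transcripts ordered by B6 signal its median was 0.58 in the dimmest group of either tissue, reached 1.84 in placenta and 1.89 in uterus in group 7, and was lower again in the brightest (1.21 in placenta). After rank matching, the median over transcripts was -0.09 in the placenta and -0.06 in the uterus. Strain differences are therefore given relative to this array-wide shift (rank-matched values), with the deposited values beside them. Rank matching aligns whole arrays and would not remove offsets of single transcripts left by separate processing. The strain differences below therefore cannot be credited to genotype rather than processing. Across transcripts, which are not independent replicates, arrays of the same group correlated with r = 0.960 (placenta B6), 0.985 (placenta R3), 0.965 (uterus B6) and 0.980 (uterus R3).

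**Figure D1:**
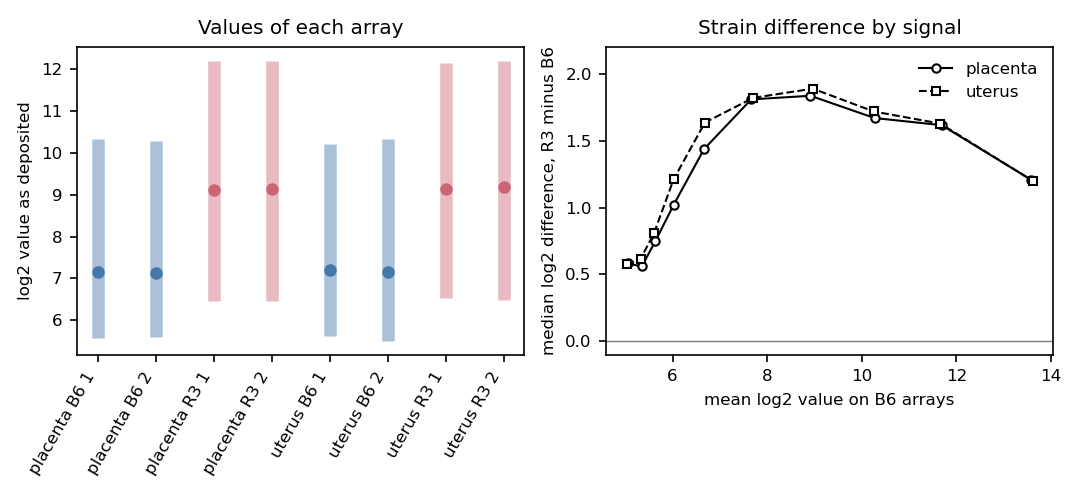
Array medians with quartile bars (log2 signal) of the 8 arrays, B6 in blue and R3 in red, and the median R3 minus B6 difference (log2) in 10 groups of transcripts ordered by B6 signal in each tissue. The 4 R3 medians lie between 9.12 and 9.18 and the 4 B6 medians between 7.12 and 7.19.

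Placenta was compared with uterus to describe what sets the organs apart in both strains. Among named genes, the pregnancy-specific glycoprotein Psg27 had the largest rise and was higher by 9.38 ± 0.23 (SE; adjusted p = 1.37e-06), the trophoblast gene Plac1 by 8.96 ± 0.21 and the prolactin-family hormone Prl7a2 by 8.73 ± 0.19. Psg25, Ceacam14, the hormone gene Sct, Ceacam13, Prl8a8, the placental cathepsin Cts3 and Psg18 were higher by 8.56 to 9.18. On the uterus B6 arrays Psg27 had values of 4.92 and 5.56, where the lowest values of any transcript were 4.21 and 4.34. Signal so near the floor bounds a difference, so the sizes and ranks of the largest changes are approximate. Of the largest falls among named genes, Cuzd1 differed by -8.36 ± 0.30 (adjusted p = 3.80e-06), the polymeric immunoglobulin receptor Pigr by -8.34 ± 0.34 and the matrix protein gene Dpt by -7.30 ± 0.29. Pinlyp, Slc13a1, Elapor1, the epithelial protease gene Tmprss4, Slc5a8, Sult1d1 and the mucosal chemokine Ccl28 lay between -8.20 and -7.09. In all, 2760 transcripts were higher and 2808 lower in placenta (5568), and 2555 and 2593 of these were also called after rank matching. The count was 3672 without placenta R3 array 1.

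Lists of trophoblast, the placenta's own epithelial lineage, rose in placenta. Of 29 measured genes of the giant cell and prolactin family list 27 rose (28 adjusted over the list alone), with a median of 6.40, camera adjusted p = 1.37e-21, and adjusted p = 0.0528 with an estimated correlation. Its leading members were Prl7a2, Prl2b1 (7.90), the cathepsin Ctsq (7.98) and the giant cell transcription factor Hand1 (7.77). Of 20 spongiotrophoblast and glycogen cell genes 18 rose (18 adjusted over the list alone), with a median of 7.10, camera adjusted p = 1.29e-21, and adjusted p = 0.0202 with an estimated correlation. In the labyrinth and syncytiotrophoblast list, the exchange layer of the placenta, 10 of 20 rose and 5 fell (12 and 6 adjusted over the list alone), with a median of 1.25 and camera adjusted p = 0.0291. This list had adjusted p = 0.202 with an estimated correlation and 0.0814 without placenta B6 array 1. Its members included the fusion gene Synb (7.04), its regulator Gcm1 (4.91) and the amino acid transporter Slc38a4 (3.94). Of 13 trophoblast progenitor genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), led by Cdx2 (7.87) and Tfap2c (5.89), with a median of 0.99, camera adjusted p = 0.0112, and adjusted p = 0.202 with an estimated correlation.

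Genes of yolk sac, red blood cells (fetal and maternal ones were not separated), imprinted loci and dividing cells were also higher in placenta. Of 19 yolk sac endoderm genes 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 3.63, camera adjusted p = 7.30e-12, and adjusted p = 0.0528 with an estimated correlation. Among them were the endoderm regulator Hnf4a (6.69), alpha-fetoprotein Afp (6.26) and the fibrinogen chains Fgg (7.78) and Fgb (7.27). Of 29 imprinted genes 18 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 2.06, camera adjusted p = 1.17e-08, and adjusted p = 0.0202 with an estimated correlation. Sfmbt2 (6.59), the growth restrictor Phlda2 (7.74), Zim1 (5.71) and the growth factor Igf2 (4.37) led that list. Of 19 erythroid genes 9 rose (11 and 1 fall adjusted over the list alone), including Ermap (4.13) and the red cell spectrin Spta1 (2.96), with a median of 0.93, camera adjusted p = 0.000208, and adjusted p = 0.0931 with an estimated correlation. Of 27 cell cycle genes 14 rose (18 adjusted over the list alone), including the cyclin Ccne1 (2.77) and the spindle checkpoint kinase Bub1b (1.68), with a median of 0.85, camera adjusted p = 4.18e-06, and adjusted p = 0.0365 with an estimated correlation. Of 27 hypoxia and glycolysis genes 5 rose (5 adjusted over the list alone), led by the glucose transporter Slc2a1 (1.10), with a median of 0.26, camera adjusted p = 0.0452, and adjusted p = 0.202 with an estimated correlation. That last call was lost without array 2 of placenta B6 (0.0776), of placenta R3 (0.0745), of uterus B6 (0.0646) or of uterus R3 (0.0822).

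Smooth muscle, fibroblast and matrix, macrophage, extracellular protease and uterine epithelium genes were lower in placenta, that is, higher in uterus. Of 17 smooth muscle genes 14 fell (15 adjusted over the list alone), with a median of -3.47, camera adjusted p = 5.25e-12, and adjusted p = 0.0202 with an estimated correlation. The contractile genes Myh11 (-5.57), Tagln (-5.35) and Actg2 (-4.40) and the filament gene Synm (-4.65) led them. Of 23 fibroblast and matrix genes 16 fell (16 adjusted over the list alone), with a median of -1.58, camera adjusted p = 3.49e-09, and adjusted p = 0.0202 with an estimated correlation, including elastin Eln (-6.91), Mfap4 (-5.76) and Col6a2 (-5.48). Of 18 macrophage and monocyte genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), including the mannose receptor Mrc1 (-3.36) and Adgre1 (-4.09), with a median of -2.49 and camera adjusted p = 3.49e-09. The macrophage list had adjusted p = 0.0528 with an estimated correlation. Of 26 extracellular protease and inhibitor genes 13 fell and 1 rose (15 and 1 adjusted over the list alone), including the matrix metalloproteinases Mmp3 (-4.99), Mmp7 (-5.92) and Mmp2 (-3.49), with a median of -0.87, camera adjusted p = 7.15e-06, and adjusted p = 0.157 with an estimated correlation. Of 19 uterine epithelium and gland genes 9 fell and 2 rose (9 and 3 adjusted over the list alone), including Ehf (-5.56), the water channel Aqp5 (-4.95) and Pax8 (-4.26), with a median of -0.70, camera adjusted p = 0.0114, and adjusted p = 0.157 with an estimated correlation.

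Lymphocyte and inflammatory genes were lower in placenta too. Of 27 uterine natural killer cell genes 11 fell (13 adjusted over the list alone), including Ctsw (-3.57), Nkg7 (-3.23), the granzyme Gzma (-4.79) and the receptor Ncr1 (-2.83), with a median of -0.85, camera adjusted p = 1.44e-06, and adjusted p = 0.157 with an estimated correlation. Of 19 T and B cell genes 5 fell (6 adjusted over the list alone), including Cd2 (-4.27) and Cd3e (-1.99), with a median of -0.34, camera adjusted p = 0.0173, and adjusted p = 0.157 with an estimated correlation. Of 31 interferon response genes 16 fell and 1 rose (16 and 1 adjusted over the list alone), including the immunoproteasome gene Psmb8 (-2.28), Oas2 (-2.57) and the chemokine Cxcl10 (-2.56), with a median of -1.12 and camera adjusted p = 3.08e-05. The interferon list had adjusted p = 0.202 with an estimated correlation. Of 27 inflammation genes 12 fell and 2 rose (12 and 2 adjusted over the list alone), with Saa3 (-4.22) among the falls and the adhesion molecule Sele (5.05) and the synthase Nos2 (3.70) as the rises, a median of -0.70, camera adjusted p = 0.00105, and adjusted p = 0.170 with an estimated correlation. Of 20 neural and muscle outgroup genes 5 fell (5 adjusted over the list alone), led by the striated muscle genes Acta1 (-5.10) and Tnni2 (-4.73), with a median of -0.25, camera adjusted p = 0.0452, and adjusted p = 0.165 with an estimated correlation. This outgroup lost its call after rank matching (0.0524) and without placenta B6 array 1 (0.135), placenta R3 array 1 (0.0573) or uterus R3 array 2 (0.0763).

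Camera called 19 of the 32 lists between tissues (5 with an estimated correlation, and 21 by fry). The other 13 were not called, although single members changed. Decidual stroma (24 measured) had 6 higher and 5 lower, with a median of -0.21, a mean of 0.27 and camera adjusted p = 0.979. In the steroid hormone list (23 measured, 6 higher and 9 lower, 0.332) the androgen-synthesis enzyme Cyp17a1 was higher by 7.43 and the retinoic acid hydroxylase Cyp26a1 differed by -4.71. Neutrophil genes (15 measured, 2 higher and 2 lower, 0.979) included Cxcr2 (6.11) and Lcn2 (-5.44), with a median of 0.06 and a mean of 0.11 although camera's direction was down. Complement and coagulation (37 measured, 11 higher and 11 lower) had a median of 0.11, a mean of -0.10 and adjusted p = 0.960. Angiogenic growth factor genes (24 measured, 3 higher and 4 lower, 0.332) included the VEGF receptor Flt1, higher by 2.91. The endothelial (1 higher and 1 lower of 18; 0.425), p53 and apoptosis (2 and 9 of 25; 0.106), unfolded protein (3 and 1 of 24; 0.447) and immediate early lists (3 and 4 of 18; 0.513) were not called. Nor were the oxidative phosphorylation (1 and 0 of 29, 0.979), ribosomal protein (0 and 1 of 32, 0.136), cholesterol synthesis (4 and 1 of 20, 0.425) and pancreas and ovary lists (1 and 0 of 19, 0.425).

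**Figure D2:**
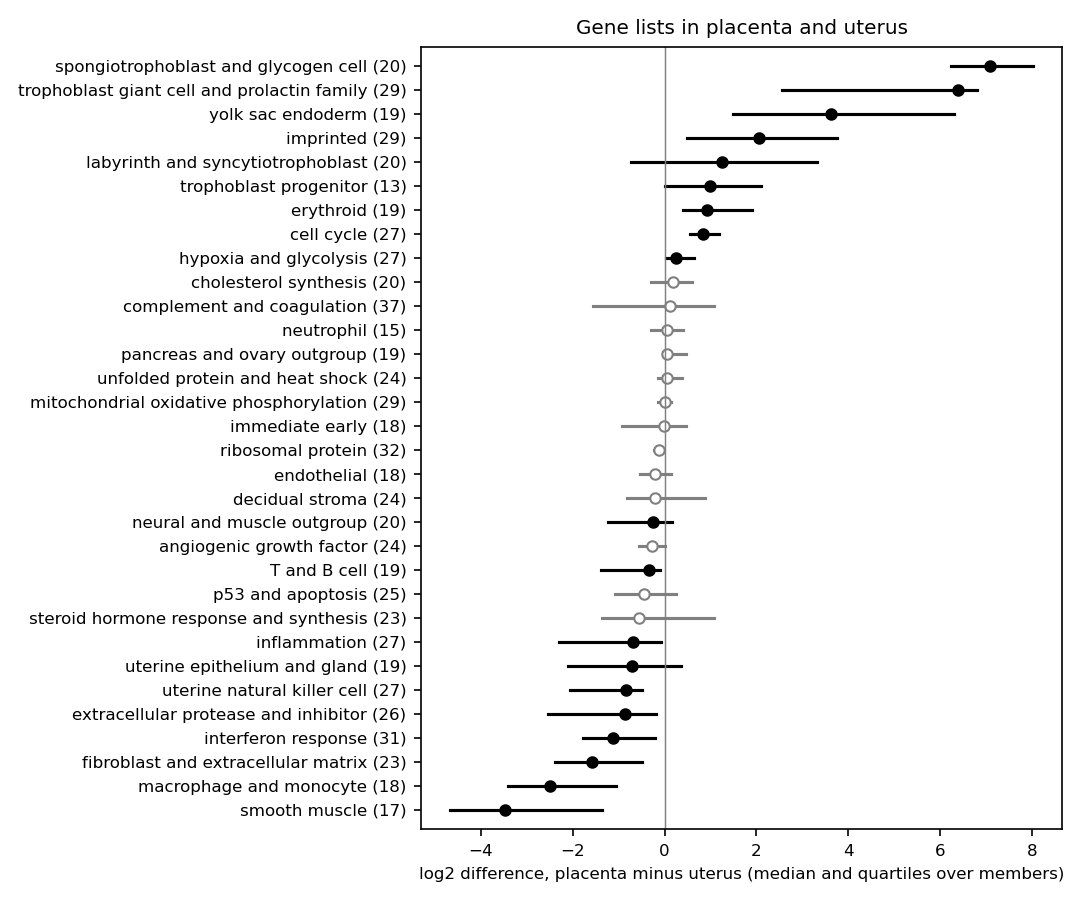
Median (point) and quartiles (bar) of the placenta minus uterus difference (log2, averaged over both strains) over the measured genes of each of the 32 lists, with the number measured in brackets and filled points where camera adjusted p was below 0.05. The medians run from 7.10 for spongiotrophoblast and glycogen cell genes to -3.47 for smooth muscle genes.

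R3 placentas were compared with B6 placentas to ask which transcripts differ at this stage in the placentas of R3 mothers. Relative to the array-wide shift, the growth arrest gene Gas1 was higher in R3 by 5.09 ± 0.48 (adjusted p = 0.0105), the vesicle fusion gene Vamp4 by 4.95 ± 0.42 (0.0105) and the small GTPase gene Kras by 4.88 ± 0.95 (0.0340). The corresponding deposited differences were 6.47, 6.36 and 6.47. Pde6d, a carrier of prenylated membrane proteins, had the largest fall among named genes, of -4.94 ± 0.43 (0.0105), and was lower in R3 even as deposited, by -3.12 ± 0.43 (0.00107). As the rule for named genes required, both R3 arrays lay outside the range of both B6 arrays for each of these genes. Other rises relative to the shift were in Gm5458, the lysosomal protease gene Ctsb, Cpeb4, the bile acid transporter Slc10a1, Prmt2, Rnf125 and Angptl3, by 4.22 to 4.97. As deposited, Bicd2, the transcription factor Elf1, the demethylase gene Phf2 and Zcchc10 were also among the 10 largest rises (5.95 to 6.07).

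Besides Pde6d, the placental falls included 7 genes that were lower in R3 on both scales. Iqcf3 fell by 2.56 relative to the shift and by 1.31 as deposited. The EGF-family ligand Areg (-2.78), Nudt8 (-2.95), the homeobox gene Nkx6-2 (-3.03), Creb3l4 (-2.35), the cytokine receptor gene Il27ra (-2.45) and the odorant receptor Olfr1270 (-1.45) fell by 0.78 to 1.51 as deposited. All 7 lay in the dimmer part of the transcripts, with a mean signal over the 8 arrays not above the median of all transcripts. What low signal contributes to these falls was not tested. Fbxo36 (-3.32), Zfp385b (-2.73), Ncln (-2.73), Nwd1 (-2.67), the anion exchanger Slc26a4 (-2.62) and Sox21 (-2.59) fell relative to the shift and did not pass as deposited (adjusted p from 0.0956 to 0.176). Of the deposited falls, Areg lost its call without array 2 of placenta B6 (0.0820) or R3 (0.0989), Creb3l4 without placenta R3 array 2 (0.0743) and Il27ra without placenta R3 array 1 (0.0942). Nudt8 lost it without placenta B6 array 2 (0.130), R3 array 1 (0.124) or R3 array 2 (0.0605), and Olfr1270 without these (0.134, 0.138 and 0.131) or either uterus R3 array (0.0597). Nkx6-2 lost it without placenta B6 array 1 (0.151) or 2 (0.0613), placenta R3 array 1 (0.0634) or 2 (0.163), or either uterus R3 array (0.0501).

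In the placenta 1123 transcripts were higher and 792 lower in R3 relative to the shift (1915), against 14085 higher and 10 lower as deposited (14095) and 1824 higher and 9387 lower with each array centred on its median. All 1123 higher and 10 of the lower transcripts were called on both the rank-matched and the deposited scale. For the rises this follows largely from the array-wide shift, which adds to most deposited differences, and is no further test of them. The rank-matched count was 0 without placenta R3 array 1 (limma, 4551 at unadjusted p below 0.05) or 2 (4033), 91 without placenta B6 array 2, 111 without either uterus R3 array, 2712 without either uterus B6 array and 3340 without placenta B6 array 1. With only the 4 placenta arrays it was 0 (6695 unadjusted). Pde6d relative to the shift had adjusted p = 0.154 and 0.178 without placenta R3 arrays 1 and 2, and kept its deposited call in each of these fits.

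R3 uteri were compared with B6 uteri to ask which maternal transcripts differ at the same stage. Relative to the shift, the transcription factor Elf1 was higher in R3 by 5.45 ± 0.65 (adjusted p = 0.0198), the carbonic anhydrase Car12 by 4.74 ± 0.55 (0.0196), the helicase gene Dhx33 by 4.72 ± 0.42 (0.0129) and Vamp4 by 4.46 ± 0.42 (0.0137). Their deposited differences were 7.04, 5.92, 5.97 and 6.16. Car12 and Dhx33 lay in the dimmer part of the transcripts, and Vamp4 had deposited values of 6.02 and 6.33 on the uterus B6 arrays. The sizes of these 3 rises are therefore approximate. Gas1, Phf2, the secreted neural glycoprotein gene Olfm1, Bicd2, Fam53c and Ankra2 were higher by 4.15 to 4.35 relative to the shift. The deposited rise of Tnfaip8l3 was 5.90. Kras, higher by 6.14 as deposited, had a rank-matched difference of 4.55 ± 0.95 that did not pass (0.0595). Pde6d again had the largest fall among named genes, of -4.21 ± 0.43 relative to the shift (0.0178) and -2.30 ± 0.43 as deposited (0.00366). As the rule for named genes required, both R3 arrays lay outside the range of both B6 arrays for each of these genes.

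Further uterine falls were smaller. Tmem171 fell by 2.83 relative to the shift, the phospholipase gene Pla2g12a by 2.74, the potassium channel gene Kcnj16 by 2.69, Usp40 by 2.67 and the tight junction gene Cldn3 by 2.62. Fcamr, R3hdm4, Adtrp and Prr15 fell by 2.50 to 2.67. As deposited, Tmem171, Usp40, Cldn3, Fcamr, R3hdm4, Adtrp and Prr15 did not pass, with adjusted p from 0.0558 to 0.224. The BMP antagonist gene Grem1 (-1.36, 0.0456), Kcnj16 (-1.03, 0.0313), the keratin Krt90 (-0.93, 0.0351), Olfr1196 (-0.84, 0.0301) and Pla2g12a (-0.75, 0.0408) fell as deposited, and Grem1 did not pass relative to the shift (-2.54, 0.0589). Grem1, Kcnj16, Krt90 and Olfr1196 lay in the dimmer part of the transcripts. Pla2g12a has 2 transcript records with uterine differences of -0.75 and 1.32, and their average was 0.28. Kcnj16 lost its deposited call without uterus B6 array 1 (0.0650) or 2 (0.120) or uterus R3 array 1 (0.173), and Krt90 without uterus B6 array 1 (0.152), uterus R3 array 1 (0.129) or 2 (0.0892), or either placenta R3 array (0.0588). Olfr1196 lost it without uterus B6 array 1 (0.0936) or 2 (0.0670), or uterus R3 array 1 (0.131) or 2 (0.0660). Grem1 lost it without uterus B6 array 2 (0.228), uterus R3 array 1 (0.0891) or 2 (0.172), either placenta B6 array (0.0649) or either placenta R3 array (0.0625). Pla2g12a lost it without uterus B6 array 1 (0.0566) or 2 (0.147), either uterus R3 array (0.119) or either placenta R3 array (0.0693).

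In the uterus 345 transcripts were higher and 122 lower in R3 relative to the shift (467), against 14755 and 8 as deposited (14763) and 1256 and 8319 with each array centred on its median. All 345 higher and 6 of the lower transcripts were called on both the rank-matched and the deposited scale, which for the rises again follows largely from the shift. The rank-matched count was 0 without uterus B6 array 1 (limma, 4063 at unadjusted p below 0.05), uterus R3 array 1 (4050) or 2 (2880) or either placenta R3 array (4552), 757 without either placenta B6 array and 1196 without uterus B6 array 2. With only the 4 uterus arrays it was 0 (5384 unadjusted). Pde6d relative to the shift had adjusted p = 0.0805 without uterus B6 array 1, 0.0830 and 0.185 without uterus R3 arrays 1 and 2, and 0.0726 without either placenta R3 array.

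The strain difference was also averaged over both tissues, which does not by itself show that a gene differs in each. The genes of smallest p relative to the shift were Heatr5a, higher in R3 by 3.66 ± 0.18 (adjusted p = 0.000971), the ubiquitin ligase gene Rnf125 (3.64 ± 0.19), the histone gene H3f3a (3.51 ± 0.19), the transcription factor Zbtb7a (3.38 ± 0.18) and the mitochondrial ribosome gene Mrpl57 (3.29 ± 0.18). The mitochondrial carrier Slc25a16, Harbi1, Olfm1, Ankra2 and the splicing factor Srsf2 were higher by 2.88 to 4.15, and the mediator subunit Med31 (2.91) and Vamp4 (4.71) were among the 10 of smallest p as deposited. Olfm1 has 3 transcript records whose deposited averaged differences ran from 1.35 to 5.59. Of these, Heatr5a, H3f3a, Slc25a16, Harbi1, Zbtb7a, Mrpl57, Ankra2, Olfm1, Rnf125 and Vamp4 led the genes higher in both tissues. Their rank-matched differences ran from 3.03 to 4.95 in the placenta and from 2.98 to 4.46 in the uterus.

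Pde6d had the smallest p among the falls on both scales, with -4.57 ± 0.30 relative to the shift (0.00149) and -2.71 ± 0.30 as deposited (0.000204). Its mean deposited signal was 13.25 in B6 and 10.12 in R3 placenta, and 12.30 in B6 and 10.01 in R3 uterus. Iqcf3 (-1.98), Nkx6-2 (-2.73), Areg (-1.84) and Olfr1196 (-1.30), all in the dimmer part of the transcripts, also fell on both scales. As deposited, Areg lost this averaged call without placenta B6 array 2 (0.0780), placenta R3 array 2 (0.0914), uterus B6 array 1 (0.0792) or uterus R3 array 2 (0.0876). Nkx6-2 lost it without placenta B6 array 1 (0.0590), placenta R3 array 2 (0.0609) or uterus R3 array 2 (0.0571), and Olfr1196 without placenta B6 array 2 (0.0527), placenta R3 array 1 (0.0981), uterus B6 array 1 (0.0601) or uterus R3 array 1 (0.0821). Pla2g12a (-2.34), the ribosome assembly factor Eif6 (-1.96), AU040320 (-2.02), Nsmce3 (-2.08), the decidual signalling gene Wnt4 (-1.77), Znhit1 (-2.06), Il27ra (-1.88) and the cytokine receptor gene Csf2rb (-1.98) fell relative to the shift. These 8 did not pass as deposited, with adjusted p from 0.119 to 0.945 and a deposited difference of 0.16 for Wnt4, and a second record of Pla2g12a and of AU040320 had deposited averaged differences of 1.24 and 1.67. Cldn3 (0.0515 as deposited), Fbxw24 (0.0517), Glrp1 (0.0546), Ppfia3 (0.0633) and Mon1a (0.0689) fell relative to the shift alone.

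Averaged over the tissues, 2475 transcripts were higher and 2419 lower in R3 relative to the shift (4894), against 18570 and 9 as deposited (18579) and 2414 and 12137 with each array centred on its median. All 2475 higher and 9 of the lower transcripts were called on both the rank-matched and the deposited scale, which for the rises follows largely from the shift. On the rank-matched scale, 241 transcripts were higher in both tissues where independent lists would share 15.1, and 60 were lower in both where 3.77 would be shared. The lists are not independent, since both come from 1 fit with a shared variance estimate per transcript. Any processing offset tied to strain would also enter both, so the excess does not show a strain effect found again. Across transcripts, which are not independent replicates, the rank-matched differences of the tissues correlated with r = 0.659 (rho = 0.606), and the deposited ones with r = 0.730 (rho = 0.712). The rank-matched count was 1208 without placenta R3 array 1, 644 without placenta R3 array 2, 3074 without uterus B6 array 1, 2131 without uterus R3 array 1 and 853 without uterus R3 array 2.

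**Figure D3:**
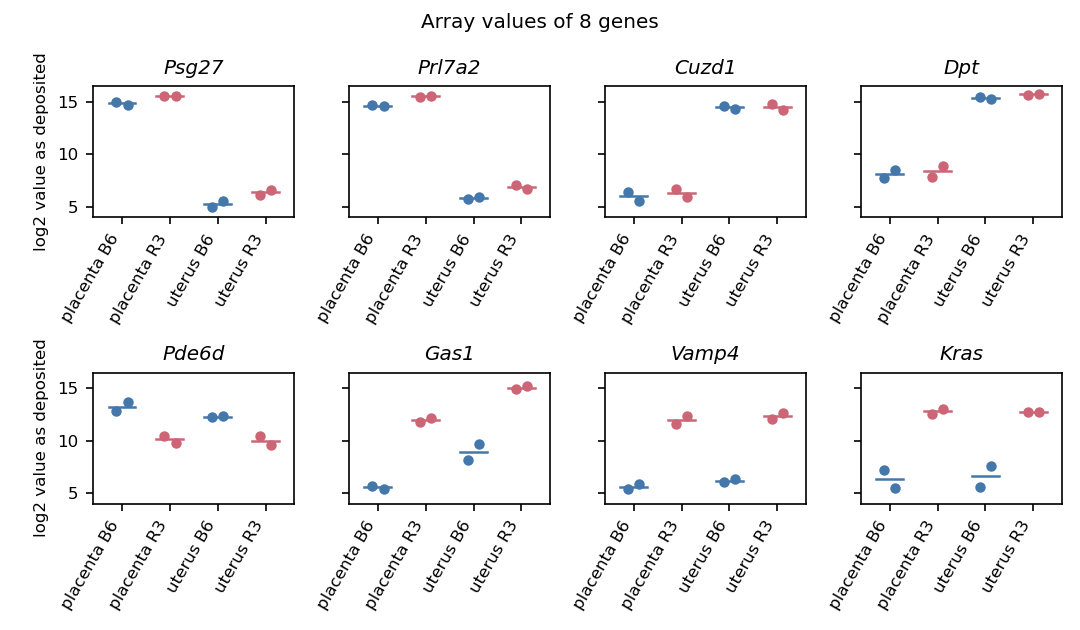
Deposited log2 signal of each array (points, 2 per group) with group means (lines) for Psg27, Prl7a2, Cuzd1, Dpt, Pde6d, Gas1, Vamp4 and Kras. Pde6d has R3 means (10.12 in placenta and 10.01 in uterus) below its B6 means (13.25 and 12.30), while Gas1, Vamp4 and Kras have R3 means above their B6 means.

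The gene lists were also compared between the strains. Camera called none of the 32 lists in the placenta, the uterus or the average as deposited: 5, 5 and 3 had unadjusted p below 0.05, the smallest adjusted p were 0.0538, 0.178 and 0.0612, and fry, which does not compare a list with other genes, called 32 in each. In the uterus, relative to the shift, camera called smooth muscle genes higher in R3 (median 0.55, adjusted p = 0.0179, and adjusted p = 0.726 with an estimated correlation) and cholesterol synthesis genes lower (median -0.70, against 1.16 as deposited, adjusted p = 0.0179, and adjusted p = 0.870 with an estimated correlation). Of the 17 smooth muscle genes 1 rose (3 adjusted over the list alone), the calcium pump regulator Pln (2.92, 0.0284), and the actin Acta2 had 1.72 (0.0648). Pln lost its call without either placenta R3 array (0.0987), uterus B6 array 1 (0.111) or uterus R3 array 1 (0.0830) or 2 (0.212). Of the 20 cholesterol genes 0 passed over all transcripts, while 5 fell and 1 rose adjusted over the list alone, and the reductase Dhcr7 had -2.04 (0.0555). The smooth muscle call was lost without uterus B6 array 2 (0.183) or uterus R3 array 1 (0.122), and the cholesterol call without uterus B6 array 2 (0.183) or uterus R3 array 2 (0.0790). Without uterus R3 array 2, camera called the giant cell and prolactin family list higher in R3 in the uterus (0.00184) and in the average (0.00194).

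Relative to the shift, camera called no list in the placenta (5 at unadjusted p below 0.05, smallest adjusted p 0.114, 1 by fry) or in the average (4, 0.308, 2 by fry). Interferon response genes had 7 higher and 2 lower of 31 in the average (8 and 2 adjusted over the list alone; camera adjusted p = 0.308). The antiviral synthase gene Oas3 was higher by 3.77 ± 0.30 (0.00213), and Ifi35 fell by 1.49 (0.00626) where its deposited difference was 0.30. The interferon list passed in the placenta without placenta R3 array 1, both relative to the shift (0.00893) and as deposited (0.000915), where it also passed without either uterus B6 array (0.0479). As deposited it passed in the average without placenta R3 array 1 (0.00962). Yolk sac genes passed relative to the shift in the placenta without placenta B6 array 1 (0.0195) or placenta R3 array 2 (0.0111), and endothelial genes, as a fall, without placenta R3 array 2 (0.0330). The outgroup lists lay lower than other genes as deposited without single arrays. For the pancreas and ovary list this held in the placenta without placenta B6 array 2 (0.0155) or either uterus B6 array (0.0479), and in the average without placenta B6 array 2 (0.00905), placenta R3 array 1 (0.0328), uterus B6 array 2 (0.0263) or uterus R3 array 1 (0.0361). For the neural and muscle list it held in the placenta without placenta B6 array 1 (0.0211) or either uterus B6 array (0.0479).

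The interaction asked whether the strain difference itself differs between placenta and uterus. The transporter Slco1b2 had the smallest p, with a strain difference higher in placenta by 4.46 ± 0.37 (adjusted p = 0.0660), and the cell adhesion gene Pcdhb2 had -3.55 ± 0.37 (0.0818). Slc25a21, the transcription factor Pitx2, Ugt8a and Slc25a31 (2.87 to 3.85) followed on the positive side, and Umod (-4.29), the glutamate receptor Gria1 (-3.12), Tmprss11a (-3.40) and the chemokine Cxcl5 (-4.39) on the negative side, all with adjusted p = 0.0871. Every gene named here lay in the dimmer part of the transcripts and had no value once that part was left out. The sizes of these differences thus rest on low signal. The count of transcripts past the threshold was 0 in limma, with 2066 at unadjusted p below 0.05 (940 positive and 1126 negative). With rank-matched values it was again 0, with 1689 unadjusted and a smallest adjusted p of 0.432. Simulated interactions of log2 size 2 were not recovered at this number of arrays. The simulation changed few transcripts and held no array-wide shift, so it does not settle which sizes were detectable in these data. The count of 0 likewise does not show that such differences are absent.

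Strain differences were also placed along the chromosomes of the assembly GRCm38.p6, since the Mus spretus segments of R3 lie in blocks. The main test ranked genes by p on deposited values, where the array-wide shift left 18570 transcripts called higher in R3. Such a ranking could miss blocks, so a count near that of random draws does not show that blocks are absent. Among the 200 genes of smallest p in the averaged comparison, at most 4 lay among 20 neighbouring genes (Morc4, Rbm41, Tsc22d3 and Nxt2 on chromosome X, between Trap1a and Nxt2), where random draws gave a median of 3 (permutation test, 10000 draws, p = 0.207). After rank matching, 5 lay there, with Prps1 added (p = 0.0101), and 5 also lay there without placenta R3 array 1 (permutation p = 0.0101). The densest stretch stayed there without placenta R3 array 2 or uterus R3 array 2 (permutation p = 0.207 for each). It lay on chromosome 15 without placenta B6 array 1 and on chromosome 5 without uterus R3 array 1 (permutation p = 0.207 for each), on chromosome 10 without placenta B6 array 2, and on chromosome 11 without uterus B6 array 1 or 2 (permutation p = 0.976 for these 3). With fewer or with more genes of smallest p it lay on chromosome X (permutation p = 0.392 and 0.247), and with 40 neighbouring genes on chromosome 10 (0.808). Of the 200 genes with the lowest moderated t after rank matching, at most 4 were neighbours, on chromosome 7 (permutation p = 0.207). The number of chromosomes with an unequal share was 0 (Fisher's exact test, smallest adjusted p 0.269, and 0.323 after rank matching). Chromosome X passed without placenta R3 array 1 (0.0319) or uterus R3 array 1 (0.0319), and chromosome 2 without uterus B6 array 1 (0.00256).

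Around Pde6d on chromosome 1, several neighbours were low in R3, a set chosen after their values were seen. Relative to the shift and averaged over the tissues, Fbxo36 fell by 2.81 ± 0.44 (adjusted p = 0.0101), the nuclear body gene Sp100 by 2.42 ± 0.45 (0.0143), Glrp1 by 2.51 ± 0.47 (0.0148) and the deubiquitinase gene Usp40 by 1.94 ± 0.21 (0.00483). As deposited, these 4 did not pass, with adjusted p from 0.0546 for Glrp1 to 0.930 for Usp40, whose deposited difference was 0.02. Of the 100 genes within 50 measured genes on either side of Pde6d, 16 were lower and 11 higher relative to the shift, and their median was -0.18. Over all transcripts 19.1% were called in the same comparison, 2475 higher and 2419 lower. Whether the neighbours were called more often than that was not tested.

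**Figure D4:**
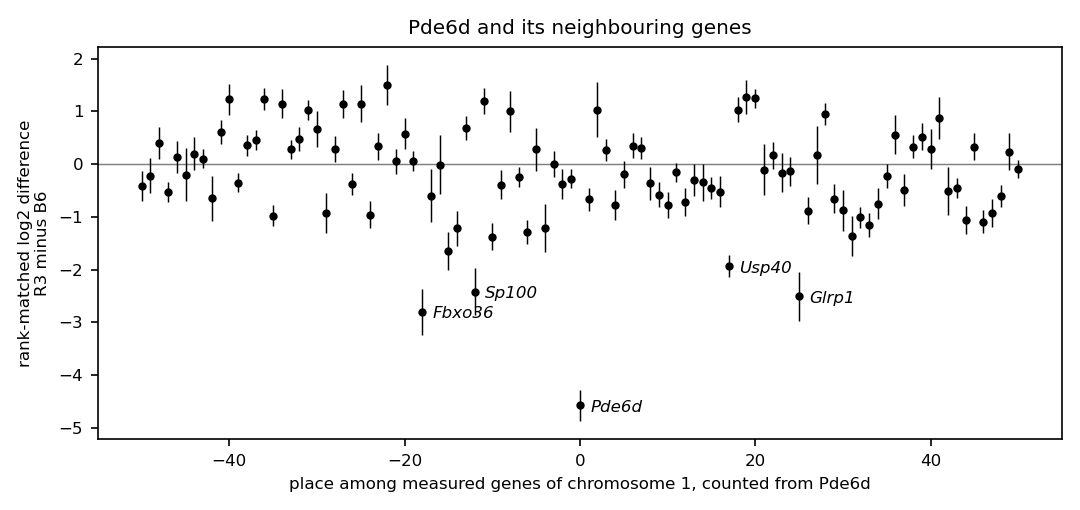
R3 minus B6 difference relative to the array-wide shift (log2, averaged over both tissues, points with SE bars) of Pde6d and of 50 measured genes on either side in chromosomal order. Pde6d lies at -4.57 and Fbxo36, Sp100, Usp40 and Glrp1 between -2.81 and -1.94, while the median of the 100 neighbours is -0.18.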

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

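In this part, the tests relative to the array-wide shift (rank-matched values), with all arrays or without single ones, were chosen after the result was seen. The yolk sac, cholesterol, fibroblast, smooth muscle and endothelial lists had a strain difference (R3 minus B6) that differed between placenta and uterus by camera's test of the interaction with all arrays, on the scale given with each, while no single gene passed the interaction test in limma (2066 at unadjusted p below 0.05).

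Yolk sac endoderm genes had a higher strain difference in placenta than in uterus, with a median of 0.91 over 19 genes as deposited (camera adjusted p = 0.000235, adjusted p = 0.535 with an estimated correlation, fry 0.293) and 1.30 relative to the array-wide shift (2.63e-05, and adjusted p = 0.626 with an estimated correlation). Its leading members on the deposited scale included the lipoprotein assembly gene Mttp (2.83), which lay in the dimmer part of the transcripts, and the endoderm regulator Hnf4a (2.34), neither past the threshold. The deposited call was lost without placenta B6 array 2 (0.0946).

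Cholesterol synthesis genes had a median of 0.64 as deposited (0.0153, and adjusted p = 0.556 with an estimated correlation) and 0.66 relative to the shift (0.00207, and adjusted p = 0.626 with an estimated correlation). The deposited call was lost without placenta B6 array 2 (0.0946), placenta R3 array 1 (0.168), uterus B6 array 2 (0.0882) or uterus R3 array 2 (0.114), and the relative call without placenta R3 array 1 (0.0769) or uterus R3 array 2 (0.0517). Fibroblast and extracellular matrix genes had a median of 0.39 as deposited (0.0153, and adjusted p = 0.535 with an estimated correlation). That call was lost without placenta B6 array 2 (0.0946), uterus B6 array 2 (0.0882) or uterus R3 array 1 (0.0541), and relative to the shift the list was not called (median 0.09, 0.716).

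Smooth muscle genes had a median of -0.80 relative to the shift (0.00107, adjusted p = 0.406 with an estimated correlation, fry 0.0318). Their strain difference was thus lower in placenta than in uterus. As deposited they did not pass (0.0532) except without placenta R3 array 2 (0.0484) or uterus R3 array 2 (0.0282). Endothelial genes had a median of -0.47 relative to the shift (0.0294, and adjusted p = 0.810 with an estimated correlation). That call was lost without placenta B6 array 1 (0.0771) or 2 (0.266), placenta R3 array 1 (0.278), uterus B6 array 1 (0.195) or uterus R3 array 1 (0.0773), and as deposited the list passed without placenta R3 array 2 (0.00245). A further 4 lists did not pass with all arrays and passed only with 1 array left out. As deposited, these were inflammation genes (0.242, and 0.0484 without placenta R3 array 2) and interferon genes (0.724, and 0.0353 without placenta R3 array 1). On the rank-matched scale, they were giant cell and prolactin family genes (0.525, and 0.00116 without uterus R3 array 1) and hypoxia genes (0.376, and 0.0483 without the same array). No group held enough arrays to test single arrays as outliers, and no array was left out of the comparisons.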

How the results depend on the processing

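In this part, quantile normalization of the transcript counts was planned, its own alternatives and the rank-matched list and chromosome counts were added after the data were seen, and the others were planned. Of 299 values of named genes, the alternatives that kept all arrays left 1697 with the same direction and side of the threshold, took the call from 107 and gave one to 52. Without single arrays these numbers were 1986, 387 and 19. The deposited uterine fall of Pla2g12a reversed to 0.28 when its 2 records were averaged, because the records differ in sign. The 20 genes named in the average relative to the shift kept call and direction in the alternatives run, except that 5 (Zbtb7a, Harbi1, Ankra2, Iqcf3 and Il27ra) had no value without the dimmer part.

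Scaling moved the strain counts. Quantile normalization gave 1915 transcripts in placenta, 467 in uterus and 4894 in the average. Against those, centring each array on its median gave 11211, 9575 (also against the deposited uterine count) and 14551. Neither scaling can separate an array-wide change in RNA from one in processing. Relative to the shift, the replicate number as a block gave 685 in placenta and 125 in uterus, and only the 4 arrays of a tissue gave 0 in each, with fewer arrays to estimate the spread. In the uterus, leaving out the dimmer part gave 904 and an intensity trend 838, for which the cause was not tested. As deposited, leaving out the dimmer part gave 11833 in the average, since fewer transcripts were tested. The block gave 13733, 14377 and 18370 in placenta, uterus and average as deposited, 5213 between tissues, 0 for the interaction and 3975 for the average relative to the shift. Strain and number as a random block gave 5257 between tissues, and the correlations of deviations between arrays of equal number ran from -0.216 to 0.103 over pairs of groups, so the number was not taken as a pairing.

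Without single arrays, deposited counts ran from 10222 to 14155 in placenta, 10986 to 15460 in uterus, 16540 to 18103 in the average and 3672 to 5618 between tissues, and stayed 0 for the interaction, with 1449 to 3170 at unadjusted p below 0.05. With all arrays the interaction count was also 0, with 885 unadjusted without the dimmer part, where fewer transcripts were tested, and 1689 to 2033 in the other alternatives. Those relative to the shift ran from 0 to 3340, 0 to 1196 and 644 to 6396. Lists called by camera ran from 0 to 3 in placenta, 0 to 0 in uterus, 0 to 2 in the average, 0 to 6 for the interaction and 17 to 19 between tissues. The highest number of neighbouring genes ran from 3 to 5, and chromosomes with an unequal share from 0 to 1.

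Fry called 32 lists in placenta, in uterus and in the average, since it does not compare a list with other genes, and 0 for the interaction. An estimated correlation left 5 lists between tissues and 0 for the interaction. Leaving out the dimmer part gave 3 lists in uterus, 1 in the average and 6 for the interaction, and rank matching gave 2 in uterus, and the cause was not tested. After rank matching, 5 of 20 neighbouring genes were among the 200 of smallest p, where the deposited values gave 4. Of 10 groups of transcripts ordered by B6 signal, the dimmest differed by a median of 0.58 in placenta, group 7 by 1.84 and the brightest by 1.21, and what dim signal contributes to this was not tested.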

Other observations

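In this part, the tests of separate normalization, of the correlation between tissues and of the placement of falls near Pde6d were chosen after the result was seen, and so was the use of rank-matched values in place of the deposited ones.

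Relative to the array-wide shift, single members of several other lists differed between R3 and B6 in the average of both tissues and kept their call without each array in turn. The stress-response gene Trp53inp1 was higher in R3 by 2.79 ± 0.24 (adjusted p = 0.00274), while 2 other genes of the p53 and apoptosis list, the death ligand Fasl (-1.55) and Cidea (-1.52), were lower. The endoplasmic reticulum chaperones Hsp90b1 (1.57 ± 0.18) and Calr (1.42 ± 0.19) were higher, as were the glycolysis regulator Pdk1 (2.29 ± 0.26) and the collagen hydroxylase P4ha2 (2.08 ± 0.30). With all arrays, other called members of the same lists were lower, Hspb1 (-1.19) of the unfolded protein list and Egln1 (-1.15) of the hypoxia list. In the oxidative phosphorylation list, Atp5j was higher by 2.86 ± 0.26 and Uqcrc1 lower (-1.76). As deposited, Fasl and Uqcrc1 had differences of 0.45 and 0.09, so their direction flips with the scale. None of these lists was called by camera.

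Genes of stroma, blood and placenta also had single changes. The matrix genes Fbln1 (2.04 ± 0.26) and Lum (1.68 ± 0.22) were higher in R3, and 5 of 23 fibroblast genes rose with none lower (camera adjusted p = 0.308, fry 0.0117). The uterine receptor gene Nr2f2 (2.04 ± 0.20), the imprinted gene Impact (2.29 ± 0.25), the T cell receptor gene Cd28 (3.04 ± 0.44), the chemokine Ccl4 (1.72 ± 0.21) and the pregnancy glycoprotein Psg16 (2.88 ± 0.38) were higher. In the spongiotrophoblast list of Psg16, the called members Phlda2 (-1.23), Ceacam11 (-1.27) and Pcdh12 (-0.97) were lower with all arrays. The cytokine brake Socs3 (-1.43) and the neutrophil granule gene Ngp (-1.63) were lower relative to the shift, with deposited differences of 0.55 and -0.25.

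R3 arrays were brighter than B6 arrays in both tissues. The arrays of each strain had nearly the same median, with a range of at most 0.0702 within a strain over both tissues against 1.99 between strains, which is what normalization of each strain's arrays as a separate set would give. Odorant and pheromone receptor transcripts (1219), whose silence in these organs was not measured, were higher by a median of 0.377 (95% interval 0.356 to 0.398), against 1.34 for the others. The bound of 0.3 set to count against more of every transcript in R3 tissue was wrong, since these transcripts lie near the floor (mean 5.28 in B6) and a rise of every transcript would include them. That rise and a difference in processing therefore cannot be told apart, because the medians argue against any normalization set with arrays of both strains.

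After rank matching, strain differences in placenta and uterus still correlated. The correlation of 0.659 across transcripts, which are not independent, is what the R3 genotype and a processing set that coincides with strain would both give, and the design confounds them, so they cannot be told apart. Gene length may account for a part: 89.2% of called transcripts stayed called once the trend with gene span was removed, just under the bound of 90 that would have counted against it. For 433 genes with several records, the strain differences of the 2 brightest records correlated across genes by 0.328 (95% interval 0.231 to 0.425) and their tissue differences by 0.808, which keeps open a difference tied to the probe set. Of 94 genes whose brightest record was called for strain, the other record was called in the same direction for 26 and the opposite for 4. Between tissues these numbers were 77 and 0 of 128 genes. Of 18 splits that keep the tissues balanced, 1, the real split, gave as many calls (4913 against 0 in the highest other), and 18 splits are too few for a share under 0.05.

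Some of the lowest deposited averaged differences in R3 lay near Pde6d. Of the 20 lowest genes, 3 (Pde6d, Glrp1 and Fbxo36) lay within 50 measured genes of it, but Glrp1 (adjusted p = 0.0546) and Fbxo36 (0.0810) did not pass as deposited. Random placement is not excluded: the densest stretch of that length anywhere held as many in a share of 0.0909 of random draws of 20 genes, and with Sp100 (adjusted p = 0.347 as deposited) the 4 of the 50 lowest were matched in 0.112 of draws, while the scan of the 200 genes of lowest moderated t on rank-matched values found its densest stretch on chromosome 7 (permutation p = 0.207), and chromosome 1 held 6 of these where 11.3 would by chance. A candidate explanation is another genome's sequence under the probes of these genes, as a Mus spretus segment could bring, but the 100 neighbours as a set were not shown to be lower than other stretches relative to the shift (rank-matched median -0.18 against -0.11 for other genes, a share of 0.321 of stretches as low). A segment carrying true differences in expression, or one shorter than the stretch tested, cannot be told apart from it without the probe sequences.

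Other splits of the arrays were counted for the averaged comparisons. Between tissues with no strain term, 2 of 35 splits gave as many calls, the real one (989) and the split by strain (15080), so the strain structure outweighs the tissue in that count and chance is not excluded by it. With strain kept in the model, 1 of 18 splits did, the real one (5261 against 0 in the highest other), and for R3 minus B6 as deposited 1 of 18 (18533 against 0), where 18 splits are too few for a share under 0.05.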
